A study of Mus musculus with 2 samples.

How the data were processed

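Bone marrow of C57BL/6 mice was measured by droplet-based single-cell 5' RNA sequencing in 2 libraries, 1 from mice given BRM014 (20 mg/kg by daily oral gavage) and 1 from mice given vehicle (10% DMSO and 1% methylcellulose), both for 14 days. Each library pooled 3 mice, whose femurs and tibias were flushed in PBS with 3% FBS 18 hours after the last dose. Per the submitters' processing notes, reads were handled with Cell Ranger 5.0.1 and STAR 2.7.2a on build mm10, and the gene annotation release is not given in the sources used here. The authors deposited raw UMI counts per gene and cell for called cells, without normalization, for 32285 genes. Each file was deposited as 2 copies with identical content, checked by comparing them, and 1 copy was used. Gene positions were taken from GENCODE vM21, which matched 32158 of the genes.

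The cell filters, clustering settings, marker genes, 17 gene lists, naming rule for genes and the first set of alternatives were chosen before the data were examined. Cells were kept with at least 300 detected genes, at most 10% mitochondrial UMIs and no doublet call by Scrublet run per library. The gene minimum left out 2297 barcodes of the BRM014 library and 2371 of the vehicle library, with a median haemoglobin share of 66.2% of UMIs in both, and the mitochondrial limit a further 17 and 11. Scrublet called 3 and 22 cells, under 0.5% of each library, so this step removed almost nothing, and removal of the highest 5% of doublet scores was added as an alternative after the data were seen. The 6405 and 6457 kept cells of the BRM014 and vehicle libraries were clustered together after scaling to 10000 UMIs and log transformation, on 2000 variable genes without immunoglobulin and T cell receptor variable genes, with 30 components, 15 neighbours and Leiden resolution 1.

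Clusters were named from 19 sets of marker genes by the highest mean standardised level. A cluster was left unnamed if under 3 markers were detected in at least 10% of its cells, if its 10 leading genes held more markers of another class, if a second lineage scored above 0.75 of the first, or if its cells had few UMIs and no marker of the class led it. Leading genes were detected in at least 25% of the cells of a cluster and ranked by fold with 10 CPM added. These naming limits were set after the data were seen. They left clusters 27 (41 and 38 cells), 28 (5 and 62) and 29 (22 and 39) unnamed. Shares of kept cells have exact Clopper-Pearson intervals.

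Within each class with at least 100 cells in each library, UMIs were summed over cells and given as CPM of the class total, with exact Poisson intervals for each sum and an exact conditional binomial interval for the ratio. A pseudocount of 0.5 UMI was added to both sums for log2 ratios. Named genes had at least 50 UMIs over both libraries and a 95% interval wholly beyond a ratio of 1.5 in either direction, ranked by the bound nearest to 1. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor, Xist, Tsix and Y-linked genes and unnamed gene models were left out. The first 12 higher and 12 lower genes were named in erythroid-like cells, the class with most cells, and the first 6 of each in 5 further classes, with Smarca2 and Smarca4 in each. Of each gene list, up to 4 members were named, those with the interval bound farthest from 1 or, where no interval excluded 1, the largest UMI sum. Where a gene had 0 UMIs in 1 library, no ratio was given.

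The lists covered SWI/SNF subunits, PU.1 and its myeloid targets, primary granule genes, secondary and tertiary granule genes, mature neutrophil genes, inflammatory cytokines and NF-kB targets, type I interferon response, MHC class II, B cell development, stem and progenitor regulators, cell cycle, immediate early and dissociation stress, p53 targets, cholesterol synthesis, oxidative phosphorylation, erythroid genes and platelet genes. A list was summarised by the median log2 ratio of members with at least 20 UMIs, if at least 3 were measured. Its percentile was taken among 10000 random lists of the same size, drawn for each member from the 50 genes on either side in mean expression, and its interval from 500 Poisson redraws of the counts.

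No p-value, standard error or count of changed genes was computed, since each group held 1 library. The intervals and naming rule were tested on simulated data with 200 changed genes per class and Poisson noise only. At a true ratio of 2, between 40.0% and 66.0% of changed genes were named over the 6 classes, at a ratio of 3 between 88.0% and 98.0%, and 0 to 4 unchanged genes per class were named. Between 3.5% and 6.5% of lists of 20 unchanged genes, drawn at random, fell outside the middle 95% of random lists. Genes that vary together were not simulated, so this does not show how often lists of such genes leave that range. Noise between mice was not simulated.

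Alternatives covered the gene and mitochondrial filters, doublet removal, Leiden resolution, separate clustering, TMM scaling with edgeR, median-of-ratios scaling, a total without dominant gene families, equal weight for cells, thinning to 1000 UMIs per cell, the pseudocount and the UMI minimums. Added after the data were seen were removal of the highest doublet scores, 1 common mix of clusters, leaving out the top cell of each gene in each library, clustering without the leading genes of 5 clusters, and classes with at least 40 cells in each library. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.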

Results

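Bone marrow cells of C57BL/6 mice were profiled by droplet-based single-cell 5' RNA sequencing after 14 days of daily oral gavage with BRM014 at 20 mg/kg or with vehicle. BRM014 is a small-molecule inhibitor of SMARCA2 (BRM) and SMARCA4 (BRG1), the ATPases that drive SWI/SNF chromatin remodelling complexes. Each group held 1 library, made from the pooled femur and tibia marrow of 3 mice collected 18 hours after the last dose. The BRM014 library held 8722 barcodes and 40472313 UMIs, with a median of 2388 UMIs per barcode. The vehicle library held 8861 barcodes and 33644437 UMIs, with a median of 2244. After filtering, 6405 cells of the BRM014 library (median 3402 UMIs and 1247 genes) and 6457 of the vehicle library (median 2957 UMIs and 1172 genes) were kept. With 1 library per group there was no replicate check and no test, so "higher" and "lower" compare these 2 libraries, and every interval is a 95% interval for counting error only. Treatment, pool of mice and library preparation could not be separated.

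The first comparison asked how the make-up of the marrow differed between the libraries. Neutrophil-like cells of all stages made up 45.8% of kept cells in the BRM014 library (exact interval 44.5% to 47.0%) and 29.7% in the vehicle library (28.6% to 30.8%). The earliest cells differed most among the myeloid-like and progenitor-like classes. Early neutrophil-like cells, which carry the primary granule genes Elane, Mpo and Prtn3, were 5.31% (4.77% to 5.89%) against 0.712% (0.522% to 0.949%), a 7.45-fold higher share. Haematopoietic stem and progenitor cell (HSPC)-like cells were 2.78% (2.39% to 3.21%) against 0.635% (0.456% to 0.860%), a 4.38-fold higher share. Both B cell-like classes and erythroid-like cells had smaller shares in the BRM014 library. Pro-B and pre-B cell-like cells were 11.9% against 17.9% and erythroid-like cells 20.4% against 28.2%. Immature and mature B cell-like cells were 5.45% against 9.31%, and 2.81% against 10.4% with the libraries clustered separately. Within the pro-B and pre-B cell-like class, cluster 20, led by Vpreb1, Igll1 and Dntt, had a higher share, 2.58% against 1.78% (ratio 1.45, 1.13 to 1.85). The ratio was 0.638 in cluster 2 and 0.423 in cluster 12.

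Immature neutrophil-like cells were 14.3% of the BRM014 library against 9.90% of the vehicle library, and mature neutrophil-like cells 26.1% against 19.1%. Monocyte-like cells had shares of 7.12% (6.50% to 7.78%) and 7.64% (7.00% to 8.31%), whose intervals overlapped, but 7.09% and 5.33% (log2 ratio 0.41) with the libraries clustered separately. Unnamed cluster 28, with 5 and 62 cells, scored highest for monocyte markers but is not counted in these shares. Among the rare classes, the ratio of shares was 2.38 (1.68 to 3.42) for plasmacytoid dendritic cell-like cells and 1.97 (1.45 to 2.705) for natural killer (NK) and innate lymphoid cell-like cells. For basophil and mast cell-like cells it was 2.95 (1.54 to 6.03), a log2 ratio of 1.56. Their log2 ratio was 4.02 (32 and 2 cells) without the highest doublet scores, and separate clustering left 38 and 0 cells. The ratio of shares was 0.504 (0.367 to 0.686) for T cell-like cells and 0.360 (0.185 to 0.663) for macrophage-like cells (log2 ratio −0.39 with separate clustering). Clusters left unnamed held 68 cells of the BRM014 library (1.06%) and 139 of the vehicle library (2.15%). HSPC-like cells had a median of 10945 UMIs in the BRM014 library and 7616 in the vehicle library, and early neutrophil-like cells 18386 and 14906. No cluster was named HSPC-like when the libraries were clustered separately or when the 5% of cells with the highest doublet scores were removed, and the log2 ratio for early neutrophil-like cells ran from 2.85 to 6.48 over the settings with cells in both libraries.

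**Figure D1:**
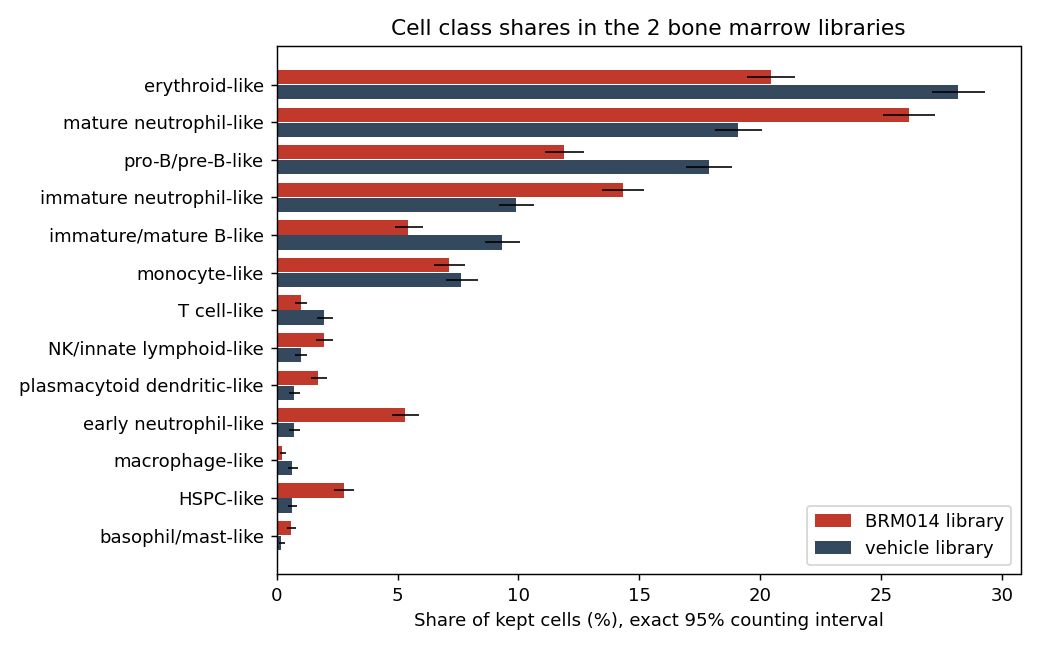
Share of kept cells (%, x axis) in each named cell class (y axis) for the BRM014 library (red) and the vehicle library (dark blue), with exact 95% counting intervals as lines. Neutrophil-like and HSPC-like shares lie higher in the BRM014 library and B cell-like, erythroid-like and T cell-like shares lower. The monocyte-like shares of 7.12% and 7.64%, which leave out unnamed cluster 28, have overlapping intervals.

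The second comparison asked how expression differed within the 6 classes with at least 100 cells in each library, beginning with the inhibited ATPases. Smarca4 (ENSMUSG00000032187, chromosome 9) stood at 1103 CPM in the BRM014 library and 1065 CPM in the vehicle library in pro-B and pre-B cell-like cells, its highest level. Its log2 ratio was −0.35 (−0.54 to −0.17) in erythroid-like cells and 0.19 (0.02 to 0.37) in monocyte-like cells, and its interval included 0 in the other 4 classes. Smarca2 (ENSMUSG00000024921, chromosome 19) had an interval that included 0 in all 6 classes, with log2 ratios from −0.22 to 0.47. The median log2 ratio of the SWI/SNF subunit list was −0.16 (0.039 relative to all genes) in erythroid-like cells, 0.069 in mature neutrophil-like, 0.050 in pro-B and pre-B cell-like, 0.16 (0.0054 relative to all genes) in immature neutrophil-like, 0.12 in immature and mature B cell-like and 0.044 in monocyte-like cells. Each of these lay within the middle 95% of random lists of matched size and expression. Over all genes the median log2 ratio was −0.20 in erythroid-like and 0.16 in immature neutrophil-like cells, and medians of lists in these 2 classes are also given relative to it.

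In mature neutrophil-like cells, stefin A family genes, which encode cystatin-type inhibitors of cysteine proteases, were the most strongly higher genes in the BRM014 library. Cstdc5 (ENSMUSG00000071561) stood at 1439 CPM against 107 CPM (13.4-fold, 11.9 to 15.1), Stfa1 (ENSMUSG00000071562) at 2837 against 277 CPM (10.2-fold, 9.51 to 11.0) and Stfa2 at 707 against 59.7 CPM (11.8-fold, 10.1 to 14.0). Csta2 was 13.6-fold and Csta3 6.15-fold higher. Penk, the precursor of enkephalin peptides, had 49 UMIs against 2, a ratio of 15.7 (4.13 to 134). The genes of the stefin A family lie side by side on mouse chromosome 16, between positions 36119946 and 36455392 of mm10.

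Of the 6 lower genes named in mature neutrophil-like cells, 3 were interferon-induced. Ifi27l2a (ENSMUSG00000079017, chromosome 12) stood at 248 CPM in the BRM014 library and 2259 CPM in the vehicle library, 9.12-fold lower (8.54 to 9.76). Rsad2, which encodes the antiviral protein viperin, was 3.77-fold lower and Oas1g, a gene of the 2'-5' oligoadenylate synthetase family, 8.31-fold lower. Cmah, an enzyme of sialic acid synthesis, was 8.66-fold lower, Bmpr1a, a BMP receptor, 8.96-fold lower and Lhx1, a homeobox gene, 7.12-fold lower. A UMI of Ifi27l2a was found in 17.0% of mature neutrophil-like cells of the BRM014 library and 65.1% of those of the vehicle library (median 2114 and 1833 UMIs per cell), and in 0.612% and 4.07% of erythroid-like cells (median 3402 and 3385 UMIs).

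In immature neutrophil-like cells the stefin A genes again led. Cstdc5 stood at 289.5 CPM against 1.41 CPM (6 UMIs in the vehicle library), a 205-fold ratio (94.0 to 559). A UMI of Cstdc5 was found in 13.5% of these cells in the BRM014 library and 0.782% in the vehicle library. For Stfa1 it was 24.6% and 2.97% (median 5929 and 5304 UMIs per cell). The intervals treat UMIs of the same cell as independent. Stfa1 was 24.1-fold, Stfa2l1 18.0-fold, Stfa3 17.4-fold and Cstdc4 8.26-fold higher. Stfa2 had 120 UMIs against 1, a ratio of 77.1 (13.6 to 3072). Lower genes were Ifi27l2a (7.74-fold), Oas1g (10.5-fold), Cmah (8.65-fold), Bmpr1a (11.7-fold), the transcriptional cofactor Lmo1 (6.41-fold) and Ica1 (6.04-fold). The stefin A genes also led cluster 14, a part of the mature neutrophil-like class with 355 cells of the BRM014 library and 9 of the vehicle library. In the other mature clusters, 1 and 4, their median log2 ratio was 2.10 and 2.58. Reads of near-identical members of this family could be split among them, so the values of single members are less certain than that of the family.

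Granule genes of neutrophils differed by granule type. The list of primary granule genes, made at the promyelocyte stage, had a median log2 ratio of 0.86 (0.58 to 1.25) in mature neutrophil-like cells, with 9 of 9 measured genes above 0. In immature neutrophil-like cells it was 0.86 (0.59 to 1.07), or 0.70 relative to all genes, with 8 of 10 above 0. Examples in the latter were the protease gene Prtn3 (143 against 42.6 CPM) and Ms4a3 (195 against 84.0 CPM), and in the former the cathepsin gene Ctsc (17.5 against 4.47 CPM). The immature value was 2.37 with no gene minimum or without the highest doublet scores, 2.43 at Leiden resolution 0.5 and 1.68 with separate clustering. Early neutrophil-like cells, which carry such genes, had a 7.45-fold higher share in the BRM014 library. RNA from them, free or in doublets, was not tested as a source of these values. The secondary and tertiary granule list was 0.16 (0.053 to 0.20) in mature cells, inside the random range (−0.034 with at most 5% mitochondrial UMIs and −0.060 with at least 500 genes per cell), and −0.030 (−0.053 to −0.0082), or −0.19 relative to all genes, in immature cells. Its members diverged. Ly6g, the antigen used to sort mouse neutrophils, was lower in both classes (298 against 695 CPM and 213 against 883 CPM), as was the collagenase gene Mmp8 in immature cells (302 against 697 CPM), while Cebpe, a regulator of granule genes, was higher in both (312 against 141 CPM and 887 against 658 CPM). With every cell weighted equally, and with doublets kept, the median in immature cells was 0.014 and 0.060.

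The list of mature neutrophil genes had medians of 0.062 and 0.22 (0.057 relative to all genes) in mature and immature neutrophil-like cells, both inside the random range, although it holds Stfa2, Stfa2l1 and Stfa3. The list of PU.1 and its known myeloid targets had medians of 0.045 and 0.25 in these classes, and 0.11 in monocyte-like cells (−0.34 with separate clustering). In immature neutrophil-like cells this was 0.095 above the median of all genes, at percentile 99.1 of random lists, and 27 of 29 genes were above 0. It fell below that median after thinning to 1000 UMIs (0.097 against 0.14) and without the highest doublet scores (0.17 against 0.24). Examples were the Src-family kinase gene Lyn (173 against 118 CPM) and Emilin2 (13.5 against 4.47 CPM). In mature neutrophil-like cells Cd14, the lipopolysaccharide co-receptor, stood at 28.01 against 7.08 CPM. The inflammatory list was 0.012 and 0.23 (0.074 relative to all genes) in these classes, with Il1b at 709 against 499 CPM and Ptgs2 at 3.83 against 11.6 CPM in mature cells. Erythroid genes had medians of 0.22 and 0.77 (0.61 relative to all genes), and Hbb-bs stood at 1975 against 1619 CPM and 1135 against 665 CPM. A UMI of Hbb-bs was nevertheless found in 27.7% of immature cells of the BRM014 library and 32.6% of those of the vehicle library (median 5929 and 5304 UMIs per cell). In immature cells the list reversed with doublets kept, without the highest doublet scores and with separate clustering, and in mature cells it was −0.41 with no gene minimum, −0.042 without the highest doublet scores and −0.95 with separate clustering.

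**Figure D2:**
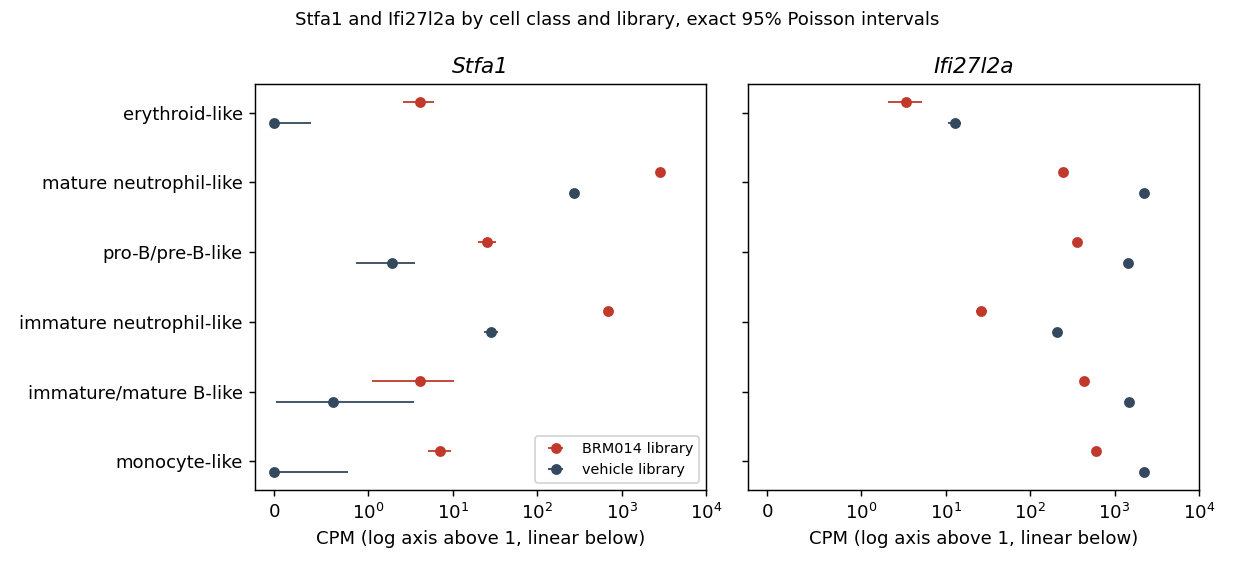
CPM (x axis, logarithmic above 1 and linear below) of Stfa1 (left) and Ifi27l2a (right) in the 6 compared classes (y axis) of the BRM014 library (red) and the vehicle library (dark blue), with exact 95% Poisson intervals as lines. In mature neutrophil-like cells Stfa1 lies at 2837 and 277 CPM and Ifi27l2a at 248 and 2259 CPM.

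In monocyte-like cells the BRM014 library had higher levels of Cd63, a granule and endosome membrane protein (54.1 against 2.77 CPM, 19.5-fold, 11.2 to 37.1), the sialic acid-binding receptor gene Cd33 (4.86-fold), the cytoskeletal gene Actn1 (7.04-fold), the iron-siderophore binding protein gene Lcn2 (3.96-fold), the decoy receptor gene Il1r2 (6.45-fold) and Rapsn (7.01-fold). The neutrophil genes S100a8 (1065 against 467 CPM) and Camp (33.3 against 13.9 CPM) were higher in this class too. Lower were Nav1 (9.25 against 59.9 CPM, 6.48-fold), Tmcc2 (7.43-fold), the lysozyme gene Lyz1 (77.0-fold), the complement gene C1qb (9.57-fold) and Ccl5 (3 UMIs against 60, a ratio of 24.4, 7.97 to 122). Retnla had 0 UMIs against 355, but all 355 were in 1 cell. The cell with most UMIs also held 45.4% of the Lyz1, 55.0% of the Ccl5 and 53.2% of the C1qb UMIs of the vehicle library, and C1qb had a log2 ratio of 0.87 without the highest doublet scores. The fibronectin gene Fn1, named once the top cell of each gene was left out, stood at 387 against 1864 CPM. Cd63 was also a leading gene of early neutrophil-like cluster 18, Lcn2 of immature neutrophil-like cluster 3 and Tmcc2 of erythroid-like clusters 6 and 9. These neutrophil-like classes had larger shares in the BRM014 library, and erythroid-like cells a smaller one. RNA from such cells, free or in doublets, was not tested as a source here.

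The primary granule list had a median of 0.43 (0.29 to 0.52) in monocyte-like cells, with 8 of 10 genes above 0. Among them were Prtn3 (1409 against 833 CPM) and Ms4a3 (50.3 against 18.1 CPM), while Mpo stood at 119.5 against 182 CPM. RNA from early neutrophil-like cells was not tested as a source here either. The cell cycle list was 0.32 (0.25 to 0.35), with 22 of 26 genes above 0 and examples in Ube2c (555 against 388 CPM) and Ccnb1 (103 against 68.2 CPM). With separate clustering, these medians were 3.06 and 3.76, but 0.21 and 0.089 with 1 common mix of clusters. This class was made up of cluster 5, with 282 cells of the BRM014 library and 352 of the vehicle library, and cluster 15, with 174 and 141. The inflammatory list was −0.22 (−0.33 to −0.039), with 12 of 15 genes below 0, led by the chemokine gene Cxcl10 (21.3 against 54.2 CPM). The MHC class II list had a median of −0.082 inside the random range, with H2-Eb1 (86.7 against 260.0 CPM), H2-Aa (151 against 340.4 CPM) and H2-Ab1 (128 against 264 CPM) below 0 and H2-Oa (13.8 against 2.35 CPM) above. It was 2.11 without the highest doublet scores and −0.98 with separate clustering. Erythroid genes had a median of −0.98, with Hba-a1 at 618 against 1222 CPM.

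In pro-B and pre-B cell-like cells, genes of early B cell development were higher in the BRM014 library. That list had a median log2 ratio of 0.33 (0.24 to 0.37), with 25 of 27 genes above 0, and 0.19 once the clusters were weighted alike. The surrogate light chain genes Vpreb2 (143 against 46.4 CPM), Vpreb1 (969 against 548 CPM) and Igll1 (1211 against 712 CPM) and the interleukin-7 receptor gene Il7r (659 against 410.2 CPM) were its leading members. The list of p53 targets had a median of 0.59 (0.36 to 0.80), with 11 of 12 genes above 0, including the cell cycle inhibitor gene Cdkn1a (61.0 against 38.8 CPM), Ccng1 (77.1 against 48.3 CPM) and Phlda3 (9.73 against 2.75 CPM). The cell cycle list was −0.11 (−0.15 to −0.059), with 23 of 26 genes below 0, and 0.038 with the same weighting. Clusters 2, 12 and 20 made up this class, with 480, 117 and 165 cells in the BRM014 library and 759, 279 and 115 in the vehicle library.

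Single genes higher in pro-B and pre-B cell-like cells were the protocadherin gene Pcdh9 (31.4 against 1.27 CPM, 24.8-fold, 10.9 to 69.4) and the cytokine signalling inhibitor Cish (7.81-fold). Cstdc4 (19.2-fold), Stfa1 (13.6-fold) and Stfa2l1 (10.4-fold) were also named, but 57.9%, 36.2% and 45.8% of their BRM014 UMIs came from 1 cell each. The interferon-inducible GTPase gene Iigp1 (13.3-fold) had 77.8% of them in 1 cell, and a log2 ratio of −2.11 after thinning. Lower genes were Ifi27l2a (364 against 1443 CPM, 3.97-fold), the proteasome activator gene Psme4 (54.3 against 156 CPM, 2.88-fold), Oaf (7.69-fold) and Rasl10a (6.50-fold). The eosinophil granule gene Prg2 was 80.2-fold lower, but 1 vehicle cell held 99.7% of its UMIs, and its log2 ratio was 1.47 with the top cell left out and 1.93 without the highest doublet scores. Ccl5 had 0 UMIs against 159, of which 96.9% were in 1 cell.

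MHC class II genes had a median of −0.30 in pro-B and pre-B cell-like cells, with H2-Eb1 (30.7 against 60.6 CPM) and H2-Aa (76.8 against 132 CPM) as examples, and −0.14 in immature and mature B cell-like cells, with Cd74 at 14868 against 16571 CPM. In the latter the median was 0.79 with separate clustering. There the B cell development list had a median of 0.060 inside the random range, with Ebf1 at 1167 against 999 CPM. The cell cycle list was 0.35 (0.19 to 0.62), with 19 of 25 genes above 0 and Ube2c at 112 against 50.4 CPM, but −0.28 with no gene minimum and −0.84 with separate clustering. The inflammatory list was −0.19 (−0.45 to −0.030), with 9 of 10 genes below 0, led by the activation marker Cd83 (46.7 against 93.3 CPM) and the adhesion molecule gene Icam1 (34.5 against 69.7 CPM). Lower single genes were Ifi27l2a (3.37-fold), the NF-kB regulator Nfkbid (46.7 against 185 CPM, 3.97-fold), Ly6a, which encodes Sca-1 (3.45-fold), Slfn5 (3.83-fold), Lynx1 (2.69-fold) and Ly6c2 (3.06-fold). Of the 105 Ly6c2 UMIs of the vehicle library, 63 were in 1 cell, and the log2 ratio was 0.17, 0.35 and 0.20 with no gene minimum, at most 5% mitochondrial UMIs and doublets kept. Genes of neutrophils led the higher side, namely Retnlg (20.3-fold), S100a8 (5.30-fold), S100a9 (3.998-fold) and Lcn2 (5.53-fold), but 1 cell held 91.4%, 76.2%, 67.5% and 57.4% of their BRM014 UMIs. A UMI of S100a8 was found in 24.1% and 21.8% of these cells in the BRM014 and vehicle libraries (median 2334 and 2354 UMIs per cell). S100a6 (5.86-fold) and Anxa2 (4.81-fold) were also higher.

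In erythroid-like cells, the apolipoprotein L genes Apol11b (958 against 270.3 CPM, 3.54-fold, 3.38 to 3.72), Apol11a (6.41-fold) and Apol10a (3.24-fold) were higher in the BRM014 library. So were Slc25a39, a mitochondrial carrier gene (1568 against 809 CPM, 1.94-fold), the phosphatase gene Phospho1 (2.29-fold), the stress-induced mTORC1 inhibitor gene Ddit4 (3.87-fold), the NF-kB inhibitor gene Nfkbia (2.41-fold), the corepressor gene Cbfa2t3 (2.17-fold) and the MHC class I genes H2-Q6 (3.58-fold) and H2-Q7 (2.43-fold). Ifitm1 (22.8-fold) and Stfa2l1 (10.2-fold) were also named, with 64.9% and 51.0% of their BRM014 UMIs in 1 cell. Lower were Enpp3 (2 UMIs against 67, a ratio of 20.9, 5.57 to 176), Fcna (8.87-fold), the interferon-induced Oas1a (5.61 against 28.5 CPM, 5.09-fold), Aldh1a7 (6.94-fold), the ubiquitin ligase gene Mid1 (9.05-fold), Ly6d (4.96-fold) and F8a (5.35-fold). The disulfide isomerase gene Pdia2 (3.47-fold), the peroxisomal thiolase gene Acaa1a (4.197-fold), the pyruvate dehydrogenase kinase gene Pdk1 (4.25-fold), the metal transporter gene Slc39a8 (3.52-fold) and the tachykinin gene Tac2 (3.09-fold) were lower too. Fcna was also a leading gene of macrophage-like cluster 30, and Ly6d of immature and mature B cell-like cluster 7. Both classes had smaller shares in the BRM014 library, and RNA from such cells was not tested as a source here.

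Gene lists in erythroid-like cells are given with the value relative to all genes second. The oxidative phosphorylation list was −0.38 (−0.44 to −0.35), or −0.18, with 25 of 25 genes below 0, among them Cox7c (249 against 371 CPM), and −0.11 with 1 common mix of clusters. Clusters of this class differed in their mix, with 86 and 218 cells of the BRM014 and vehicle libraries in cluster 16, 157 and 300 in cluster 9 and 164 and 129 in cluster 19. Erythroid genes were 0.26, or 0.46, inside the random range, with 15 of 16 above 0, Alas2, the first enzyme of haem synthesis, at 4568 against 3474 CPM, and the carbonic anhydrase gene Car1 below 0 at 375 against 603 CPM. The list of p53 targets was 0.25 (0.026 to 0.38), or 0.46, with 7 of 9 genes above 0, but only 3 by their intervals and 1 below, and it was 0.019 without the highest doublet scores and 0.023 with list members from 1 UMI. The inflammatory list was 0.78 (0.21 to 1.27), or 0.99, but only 6 members were measured, and the interval of 2, Nfkbia and Relb, excluded 0. The cell cycle list was 0.039, or 0.24, inside the random range, although the replication licensing genes Mcm3, Mcm4, Mcm5 and Mcm7 lay below 0 (Mcm3 171 against 256 CPM).

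The median of the type I interferon response list was below 0 in each of the other 5 compared classes. It was −0.82 (−1.16 to −0.65), or −0.98 relative to all genes, in immature neutrophil-like cells, with 17 of 18 genes below 0 (13 by their intervals), and −0.80 (−0.95 to −0.66) in mature neutrophil-like cells, with 17 of 20 (15 by their intervals, and 1 above). It was −0.64 (−0.72 to −0.58) in monocyte-like cells (18 of 20, each by its interval), −0.58 (−0.65 to −0.22) in pro-B and pre-B cell-like cells (15 of 20, 6 by their intervals) and −0.49 (−0.87 to −0.35) in immature and mature B cell-like cells (14 of 17, 8 by their intervals). In the B cell classes 1 interval each lay above 0, that of Ifit1 in pro-B and pre-B cell-like cells (1.29, 0.032 to 2.64) and that of Ifitm3 in immature and mature B cell-like cells (0.92, 0.31 to 1.55). The list median of the latter class was −0.14 with no gene minimum and −0.88 with list members from 1 UMI. In monocyte-like cells it lay further below 0 with separate clustering. With 1 common mix of clusters it was −0.50 there and −0.51 in mature neutrophil-like cells. Each of the 5 medians lay below all 10000 random lists. In erythroid-like cells the median was −0.31, or −0.10 relative to all genes, inside the random range at percentile 4.82, with 15 of 17 genes below 0. Examples were Rtp4 (12.9 against 54.8 CPM in immature neutrophil-like cells), Ifit1 and Ifit3 (20.1 against 66.4 CPM and 22.7 against 67.5 CPM in mature neutrophil-like cells) and Rsad2 (15.2 against 70.4 CPM in monocyte-like cells).

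**Figure D3:**
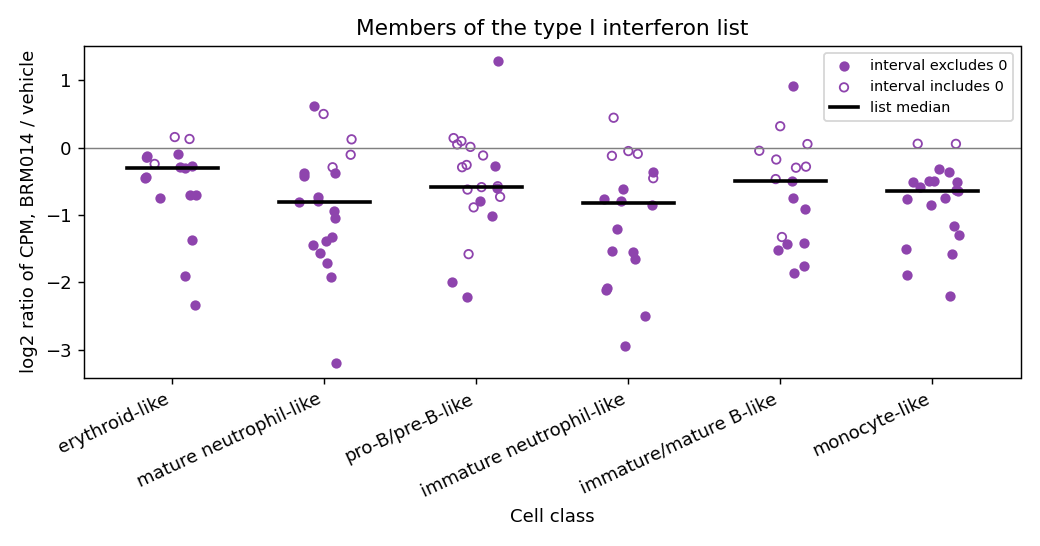
Log2 ratio of CPM, BRM014 over vehicle (y axis), of each measured member of the type I interferon list in the 6 compared classes (x axis). Each point is 1 gene, filled where its 95% counting interval excludes 0, and black lines are list medians, from −0.82 in immature neutrophil-like cells to −0.31 in erythroid-like cells.

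The median of cholesterol synthesis genes was below 0 in mature and immature neutrophil-like and in monocyte-like cells. It was −0.82 (−1.16 to −0.52) in mature neutrophil-like cells (9 of 10 genes below 0, 6 by their intervals), −0.41 (−0.74 to −0.31), or −0.57 relative to all genes, in immature neutrophil-like cells (14 of 15, 8 by their intervals) and −0.41 (−0.51 to −0.20) in monocyte-like cells (18 of 19, 8 by their intervals). The size varied with the setting, from −1.26 (at least 500 genes per cell) to −0.33 (Leiden resolution 2) in mature neutrophil-like cells and from −0.88 (doublets kept) to −0.13 (Leiden resolution 0.5) in immature neutrophil-like cells, and it was −0.13 in monocyte-like cells with separate clustering. An example was the sterol demethylase gene Cyp51 (2.27 against 8.002 CPM) in immature neutrophil-like cells. The median was −0.53 in erythroid-like cells, or −0.33 relative to all genes (−0.081 with 1 common mix of clusters), −0.26 in immature and mature B cell-like cells and 0.011 in pro-B and pre-B cell-like cells, and no member's interval excluded 0 in either B cell class. The oxidative phosphorylation list was −0.19 in pro-B and pre-B cell-like cells, with 25 of 25 genes below 0, −0.096 in monocyte-like and −0.078 in immature and mature B cell-like cells, 0.15 in mature neutrophil-like cells and 0.14 in immature neutrophil-like cells, or −0.022 relative to all genes (−0.010 with TMM and −0.013 with median-of-ratios scaling). The B cell-like value was above 0 with no gene minimum, at most 5% mitochondrial UMIs or doublets kept, and the monocyte-like value with separate clustering.

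Immediate early and dissociation stress genes had medians of 0.11 (0.31 relative to all genes) in erythroid-like, 0.19 in mature neutrophil-like, 0.066 in pro-B and pre-B cell-like, 0.22 (0.065 relative to all genes) in immature neutrophil-like, 0.097 in immature and mature B cell-like and −0.042 in monocyte-like cells, all inside the random range. Single members differed, with Fos at 146 against 248 CPM in mature neutrophil-like cells and Egr1 at 48.7 against 125 CPM in immature and mature B cell-like cells. The p53 list was −0.016 in mature neutrophil-like, 0.057 (−0.10 relative to all genes) in immature neutrophil-like, 0.017 in immature and mature B cell-like and −0.059 in monocyte-like cells. The cell cycle list was 0.048 and 0.23 (0.069 relative to all genes) in mature and immature neutrophil-like cells and the inflammatory list 0.17 in pro-B and pre-B cell-like cells, inside the random range. Erythroid genes were −0.051 in pro-B and pre-B cell-like and 0.11 in immature and mature B cell-like cells. The latter value was −0.48 with at most 5% mitochondrial UMIs, −0.49 with doublets kept, −0.89 without the highest doublet scores, −0.023 without the top cell of each gene and 1.34 with no gene minimum. Of the platelet list, 2 members were measured in erythroid-like cells and 0 in the other 5 classes, too few for a median.

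**Figure D4:**
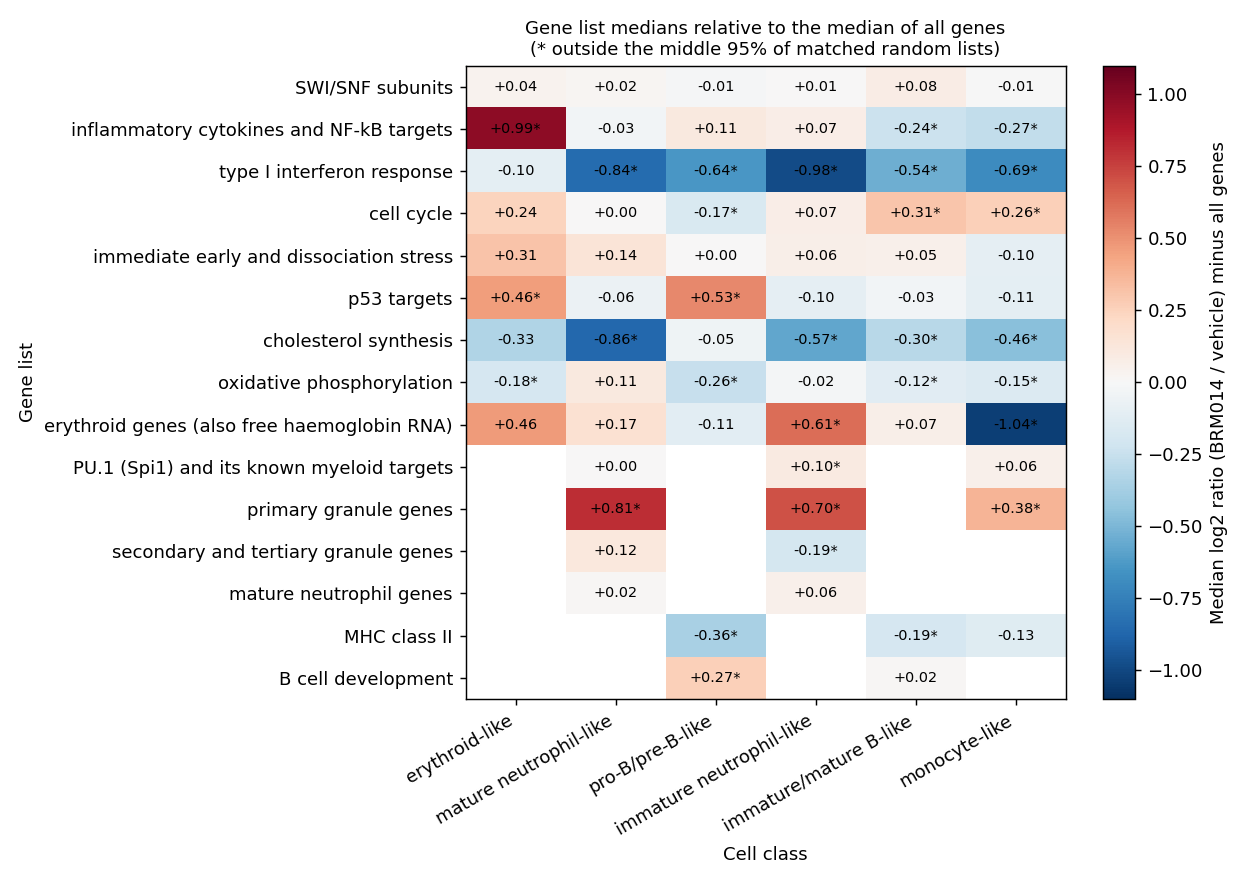
Median log2 ratio of CPM (BRM014 over vehicle) minus that of all genes, in colour and as a number, for each gene list (y axis) in each compared class (x axis), with stars outside the middle 95% of 10000 matched random lists and blanks where a list was not fitted. Interferon values run from −0.98 to −0.10, and primary granule values are 0.81, 0.70 and 0.38.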

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

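All 3 differences were noticed after the values were seen, and none was tested. They stand out because the median log2 ratio of 1 gene list lay above the middle 95% of matched random lists in some classes and below it in others. For inflammatory cytokines and NF-kB targets the median was 0.78 in erythroid-like cells, from 6 measured genes, but −0.19 in immature and mature B cell-like and −0.22 in monocyte-like cells. For cell cycle genes it was 0.35 in immature and mature B cell-like and 0.32 in monocyte-like cells, but −0.11 in pro-B and pre-B cell-like cells. For erythroid genes it was 0.77 in immature neutrophil-like and −0.98 in monocyte-like cells. The inflammatory value was −0.022 in immature and mature B cell-like cells with every cell weighted equally and −0.68 in monocyte-like cells with separate clustering. The cell cycle values reversed in immature and mature B cell-like cells with no gene minimum (−0.28) and with separate clustering (−0.84), and in pro-B and pre-B cell-like cells with 1 common mix of clusters (0.038), which also gave 0.089 in monocyte-like cells. The erythroid value in immature neutrophil-like cells reversed with doublets kept (−0.070), without the highest doublet scores (−0.31) and with separate clustering (−1.66).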

How the results depend on the processing

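The alternatives with the highest doublet scores removed, 1 common mix of clusters or the top cell of each gene left out were chosen after the data were seen. Of 106 log2 ratios of shares under alternatives, for 14 results, 91 stayed within the counting interval, 15 moved outside it and 0 reversed. Of 1242 list medians, for 69 results, 1007 stayed within it, 221 moved and 14 reversed. Of 1344 ratios of 84 named genes, 1159 stayed within it, 178 moved and 7 reversed. Reversed here means a change of sign in a share ratio whose interval excluded 0, a median outside the middle 95% of random lists or a named gene. Counting every result, the sign changed in 1 share ratio, 87 list medians and 7 named genes. No paired analysis and no leaving out of replicates was possible because each group held 1 library. HSPC-like cells had no value without the highest doublet scores or with separate clustering, with 0 cells in both libraries. Early neutrophil-like cells had none there, with 106 and 145 cells in the BRM014 library and 0 in the vehicle library, and basophil and mast cell-like cells none with separate clustering, with 38 and 0. The cluster matching cluster 28 had none there either, with 0 and 58. With a minimum of 10 in place of 50 UMIs, 5 of the 12 higher genes of erythroid-like cells were named again. The list medians and share ratios that moved or reversed, and the named genes that reversed, are given by setting as log2 values. The 178 ratios of named genes that moved are not listed by setting. For none of these was the cause tested.

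With at least 500 genes per cell, erythroid-like medians were cell cycle 0.092, erythroid genes 0.28. Mature neutrophil-like medians were secondary granule −0.060, mature neutrophil genes 0.24, stress 0.31, cholesterol −1.26, erythroid genes 0.63. Pro/pre-B-like medians were erythroid genes −0.10. Immature neutrophil-like medians were PU.1 0.34, mature neutrophil genes 0.60, interferon −0.62, cell cycle 0.078, erythroid genes 0.20. Share log2 ratios were immature neutrophil-like 0.86.

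With no gene minimum, erythroid-like cells gave SWI/SNF −0.27, interferon −0.49, cell cycle −0.11, cholesterol −0.68, OXPHOS −0.48, erythroid genes 0.17. Mature neutrophil-like cells gave secondary granule 0.21, erythroid genes −0.41. Immature neutrophil-like cells gave SWI/SNF 0.35, primary granule 2.37, secondary granule −0.23, cell cycle 0.54, stress 0.081, p53 0.30, cholesterol −0.19, OXPHOS 0.25, erythroid genes 0.010. B cell-like cells gave interferon −0.14, cell cycle −0.28 (reversed), cholesterol 0.0038 (reversed), OXPHOS 0.051 (reversed), erythroid genes 1.34. Ratios of shares on the log2 scale were early neutrophil-like 5.54, erythroid-like −0.24, immature neutrophil-like 0.77. Reversed genes were Ly6c2 in B cell-like cells 0.17.

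With at most 5% mitochondrial UMIs, in mature neutrophil-like cells medians were secondary granule −0.034, mature neutrophil genes 0.18, interferon −0.57, OXPHOS 0.069, erythroid genes 0.62. In immature neutrophil-like cells medians were PU.1 0.34, secondary granule −0.0029, cell cycle 0.038, cholesterol −0.31. In B cell-like cells medians were cell cycle 0.018, OXPHOS 0.0030 (reversed), erythroid genes −0.48. Share log2 ratios were immature neutrophil-like 0.76, mature neutrophil-like 0.29. Reversed genes were Ly6c2 in B cell-like cells 0.35.

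With doublets kept, for mature neutrophil-like cells values were erythroid genes 0.11. For immature neutrophil-like cells values were PU.1 0.18, primary granule 1.35, secondary granule 0.060 (reversed), cell cycle 0.33, cholesterol −0.88, OXPHOS 0.20, erythroid genes −0.070 (reversed). For B cell-like cells values were cell cycle 0.11, OXPHOS 0.0024 (reversed), erythroid genes −0.49. Ratios of shares on the log2 scale were early neutrophil-like 6.48. Reversed genes were Ly6c2 in B cell-like cells 0.20.

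At Leiden resolution 0.5, medians in immature neutrophil-like cells were SWI/SNF 0.35, primary granule 2.43, secondary granule −0.25, cell cycle 0.51, cholesterol −0.13, OXPHOS 0.24, erythroid genes 0.67. Share log2 ratios were early neutrophil-like 6.47, immature neutrophil-like 0.79.

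At Leiden resolution 2, mature neutrophil-like medians were secondary granule 0.34, mature neutrophil genes −0.033, cholesterol −0.33. Immature neutrophil-like medians were secondary granule −0.10, erythroid genes 0.67. Ratios of shares on the log2 scale were immature neutrophil-like 0.76, mature neutrophil-like 0.59.

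Without the highest 5% of doublet scores, erythroid-like cells gave p53 0.019, OXPHOS −0.47, erythroid genes 0.30. Mature neutrophil-like cells gave secondary granule 0.31, erythroid genes −0.042. Pro/pre-B-like cells gave erythroid genes −0.64. Immature neutrophil-like cells gave SWI/SNF 0.33, PU.1 0.17, primary granule 2.37, secondary granule −0.12, cell cycle 0.58, cholesterol −0.30, OXPHOS 0.19, erythroid genes −0.31 (reversed). B cell-like cells gave MHC class II −0.070, B development 0.13, cell cycle 0.14, erythroid genes −0.89. Monocyte-like cells gave primary granule 0.52, MHC class II 2.11, erythroid genes −0.76. Share log2 ratios were basophil and mast cell-like 4.02. Reversed genes were Prg2 in pro/pre-B-like cells 1.93, C1qb in monocyte-like cells 0.87.

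With separate clustering, in mature neutrophil-like cells medians were secondary granule 0.34, erythroid genes −0.95. In immature neutrophil-like cells medians were SWI/SNF 0.33, primary granule 1.68, secondary granule −0.12, mature neutrophil genes 0.050, interferon −1.32, cell cycle 0.59, stress 0.033, cholesterol −0.25, OXPHOS 0.23, erythroid genes −1.66 (reversed). In B cell-like cells medians were MHC class II 0.79 (reversed), B development −0.25, cell cycle −0.84 (reversed), stress −0.054, p53 −0.31, OXPHOS −0.24. In monocyte-like cells medians were SWI/SNF 0.41, PU.1 −0.34, primary granule 3.06, inflammatory −0.68, interferon −1.47, MHC class II −0.98, cell cycle 3.76, stress −0.56, p53 −0.23, cholesterol −0.13, OXPHOS 0.074 (reversed), erythroid genes −1.42. Ratios of shares on the log2 scale were immature and mature B cell-like −1.89, macrophage-like −0.39, monocyte-like 0.41.

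With TMM scaling, for erythroid-like cells values were SWI/SNF 0.0072, interferon −0.14, cell cycle 0.21, stress 0.28, p53 0.43, OXPHOS −0.21, erythroid genes 0.43. For mature neutrophil-like cells values were PU.1 0.012. For pro/pre-B-like cells values were SWI/SNF −0.021, cell cycle −0.18, OXPHOS −0.27, erythroid genes −0.12. For immature neutrophil-like cells values were SWI/SNF 0.017, PU.1 0.11, secondary granule −0.18, mature neutrophil genes 0.069, cell cycle 0.081, stress 0.077, OXPHOS −0.010, erythroid genes 0.62. For B cell-like cells values were MHC class II −0.20.

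With median-of-ratios scaling, medians in erythroid-like cells were SWI/SNF 0.041, interferon −0.10, cell cycle 0.24, stress 0.31, p53 0.46, OXPHOS −0.18, erythroid genes 0.47. Medians in mature neutrophil-like cells were PU.1 0.016. Medians in pro/pre-B-like cells were SWI/SNF −0.028, interferon −0.66, cell cycle −0.19, OXPHOS −0.27, erythroid genes −0.13. Medians in immature neutrophil-like cells were SWI/SNF 0.014, PU.1 0.10, secondary granule −0.18, mature neutrophil genes 0.066, cell cycle 0.078, stress 0.074, OXPHOS −0.013, erythroid genes 0.62. Medians in B cell-like cells were MHC class II −0.20.

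With a total without dominant families, erythroid-like medians were cell cycle −0.018, OXPHOS −0.44, erythroid genes 0.20.

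With equal weight for cells, erythroid-like cells gave SWI/SNF −0.076, interferon −0.51, cell cycle −0.070, stress 0.34, OXPHOS −0.22, erythroid genes 0.091. Mature neutrophil-like cells gave OXPHOS 0.075. Pro/pre-B-like cells gave inflammatory 0.33, B development 0.40, cell cycle −0.28, OXPHOS −0.31, erythroid genes −0.16. Immature neutrophil-like cells gave secondary granule 0.014 (reversed), mature neutrophil genes 0.072, erythroid genes 0.52. B cell-like cells gave inflammatory −0.022, B development 0.13, cell cycle 0.062, OXPHOS −0.15. Monocyte-like cells gave primary granule 0.65, cell cycle 0.45.

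After thinning to 1000 UMIs, in erythroid-like cells medians were interferon −0.46, cell cycle −0.074, cholesterol −0.30, OXPHOS −0.16, erythroid genes 0.075. In mature neutrophil-like cells medians were cholesterol −0.47. In pro/pre-B-like cells medians were cell cycle −0.19. In immature neutrophil-like cells medians were PU.1 0.097, primary granule 1.37, secondary granule −0.065, mature neutrophil genes 0.40, interferon −1.27, p53 0.32, cholesterol −0.81, erythroid genes 1.03. In B cell-like cells medians were SWI/SNF −0.074, cell cycle 0.12, p53 0.37. In monocyte-like cells medians were SWI/SNF 0.24, interferon −0.86, MHC class II −0.63, OXPHOS −0.16, erythroid genes −0.84. Reversed genes were Iigp1 in pro/pre-B-like cells −2.11.

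With 1 common mix of clusters, for erythroid-like cells values were SWI/SNF 0.048, cell cycle −0.017, cholesterol −0.081, OXPHOS −0.11, erythroid genes 0.13. For mature neutrophil-like cells, of clusters 1 and 4 only, values were PU.1 0.13, secondary granule 0.020, mature neutrophil genes 0.17, interferon −0.51, stress 0.28. For pro/pre-B-like cells values were B development 0.19, cell cycle 0.038 (reversed). For monocyte-like cells values were SWI/SNF −0.034, PU.1 0.18, primary granule 0.21, interferon −0.50, cell cycle 0.089.

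Without the top cell of each gene, medians in pro/pre-B-like cells were erythroid genes −0.10. Medians in B cell-like cells were cell cycle 0.073, erythroid genes −0.023. Reversed genes were Prg2 in pro/pre-B-like cells 1.47.

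With list members from 1 UMI, erythroid-like medians were p53 0.023. Immature neutrophil-like medians were interferon −1.21. B cell-like medians were interferon −0.88.

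With list members from 100 UMIs, monocyte-like cells gave MHC class II −0.93.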

Other observations

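All values in the first 2 paragraphs come from comparisons chosen after the data were seen. In early neutrophil-like cells (340 cells of the BRM014 library and 46 of the vehicle library) the primary granule list had a median log2 ratio of 2.15, with 10 of 10 genes above 0, and the secondary and tertiary granule list −1.01, with 17 of 17 below 0. Over all genes the median in this class was 0.40, and relative to it the 2 lists stood at 1.74 and −1.41. The list of stem and progenitor regulators was 0.95 in early neutrophil-like cells and −0.11 in HSPC-like cells. Cluster 26, which held 88 of the early neutrophil-like cells of the BRM014 library and 1 of the vehicle library, had Mpo, Ctsg, Elane and Prtn3 among its leading genes. Cluster 18 held 252 and 45 of them. The class thus differed in its mix of clusters, and its list medians were not adjusted for that. Elane, Mpo, Prtn3, Ctsg, Ms4a3 and Gstm1 of the primary granule list were also markers used to name the class. In HSPC-like cells the cell cycle list was 0.72, with 26 of 26 genes above 0, the primary granule list 0.86, the PU.1 list 0.47 and the platelet list 1.03 from 6 measured genes. Hbb-bs, of erythroid cells, stood at 1656 against 24.1 CPM in this class, with a UMI in 29.2% and 17.1% of cells (median 10945 and 7616 UMIs per cell), and Camp, of neutrophils, at 193 against 39.2 CPM. The interferon list was −0.026 in early neutrophil-like cells, below the median of 0.40 over all genes there. It was −0.19 in HSPC-like, −0.31 in T cell-like, −0.45 in plasmacytoid dendritic cell-like and 0.040 in NK and innate lymphoid cell-like cells. In plasmacytoid dendritic cell-like cells the cell cycle list was −0.67. Cholesterol synthesis genes, with medians below 0 in the later neutrophil stages, had a median of 0.73 (0.36 to 0.96) in early neutrophil-like cells, or 0.33 relative to all genes, inside the random range and with 16 of 18 above 0. Erythroid genes stood at 1.30 in early neutrophil-like (0.90 relative to all genes, at percentile 99.7), 4.62 in plasmacytoid dendritic cell-like, −5.43 in T cell-like and −1.39 in NK and innate lymphoid cell-like cells. A UMI of Hbb-bs was nevertheless found in 32.4% and 36.2% of plasmacytoid dendritic cell-like cells of the BRM014 and vehicle libraries (median 5947 and 5524 UMIs per cell) and in 34.4% and 29.7% of T cell-like cells (median 3765 and 4114 UMIs per cell).

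Unnamed cluster 28, which scored highest for monocyte markers and was led by Apoe, Ace, Eno3, Adgre4 and Fabp4, held 5 cells of the BRM014 library and 62 of the vehicle library. With the 50 leading genes of 5 clusters left out of the clustering, the matching cluster held 5 and 58 cells, an 11.5-fold lower share (4.66 to 36.8). With the libraries clustered separately, it held 0 and 58 cells. Over all kept cells, Ace stood at 0.746 CPM in the BRM014 library and 6.85 CPM in the vehicle library, Fabp4 at 0.612 and 5.54 CPM and Hpgd at 4.55 and 19.5 CPM. Of its other leading genes, Ear2 stood at 15.1 and 17.4 CPM and Nr4a1 at 6.74 and 9.85 CPM, and Apoc2 was higher in the BRM014 library (32.2 and 26.2 CPM). Genes of the Ly6 family between positions 74747852 and 75567255 of chromosome 15 were looked at once Ly6g, Ly6d and Ly6a had been seen. Of 24 gene and class pairs, 16 had an interval below 0 and 7 above. The share of all genes with such intervals was not computed, so these counts do not set the region apart. Ly6d was lower in 4 classes (−2.27 in erythroid-like, −0.78 in pro-B and pre-B cell-like, −0.60 in immature and mature B cell-like and −0.93 in monocyte-like cells). In the vehicle library it stood at 14.3 CPM in erythroid-like and 15.4 CPM in monocyte-like cells, against 4688 CPM in immature and mature B cell-like cells. Ly6e was higher in 5 classes, with 1.48 in immature neutrophil-like cells, and lower in erythroid-like cells at −0.32. Ly6a was −1.78 in immature and mature B cell-like and 1.59 in pro-B and pre-B cell-like cells.

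Of the tests below, those of doublets over both progenitor classes and of more UMIs per cell, with and without new clustering, were written beforehand, and all others were chosen only after the result was seen.

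HSPC-like and early neutrophil-like cells together had a higher share in the BRM014 library. More UMIs per cell was argued against by cells thinned to 1000 UMIs. Of these, 7.15% against 1.40% had at least 3 UMIs of Elane, Mpo, Prtn3, Ctsg and Ms4a3 (ratio 5.11, 4.05 to 6.51). Over all kept cells the ratio of shares of the 2 classes was 6.00 (4.77 to 7.62). It was 4.09 (3.26 to 5.20) within myeloid-like and HSPC-like cells, which argues against fewer B lymphoid and erythroid cells as the whole cause. Among the 3204 and 3341 cells of the BRM014 and vehicle libraries with the lowest doublet scores the ratio was 26.1 (6.85 to 221) for early neutrophil-like cells. Of this class, 50 of 340 cells of the BRM014 library and 2 of 46 of the vehicle library lay in that part. The cut took away more of the class in the vehicle library, where it was rarer and was scored separately. This ratio therefore cannot decide about doublets. For both classes together the ratio was 26.6, above the bound set beforehand. That bound was not enough, because the cut has the same limit and only 1 HSPC-like cell remained. Doublets thus stay open for both classes. Depth stays open for HSPC-like cells, since clustering thinned cells again named 0 HSPC-like cells. With 1 pool per group, a difference between the mice of the 2 pools cannot be told apart from the treatment.

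Stefin A family genes were higher in neutrophil-like cells of the BRM014 library. Counts shared among paralogs in 1 constant split were argued against by the share of Stfa2 among Stfa1 and Stfa2 UMIs, 2.58% (2.15% to 3.08%) in immature and 19.9% (19.3% to 20.6%) in mature neutrophil-like cells, while partial sharing stays open. A different mix of clusters as the whole cause was argued against by the lowest median log2 ratio over 5 neutrophil clusters, 2.10 (1.79 to 2.35). This test took clusters with at least 40 cells in each library. Clusters 14 and 26, with 9 and 1 vehicle cells, were too small for it. Free RNA was argued against by the mean UMIs per erythroid-like cell, 0.327% of those per mature neutrophil-like cell (upper bound 0.399%). Doublets were not tested for this pattern. The treatment and the pool of mice were not separated here either.

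The median of the type I interferon list lay below all random lists in 5 compared classes of the BRM014 library. In erythroid-like cells it was −0.31, inside the random range. Scaling was argued against in the 5 classes by their highest median with TMM or median-of-ratios scaling, −0.55 (−0.94 to −0.40). A different mix of clusters as the whole cause was argued against by their highest with clusters weighted alike, −0.50 (−0.54 to −0.42). The medians of monocyte-like and mature neutrophil-like cells shrank with this weighting, so the mix stays open as part of the cause. Only clusters with at least 20 cells in each library were weighted, which left out mature neutrophil-like cluster 14 (355 and 9 cells). For that class the value covers clusters 1 and 4 only. Erythroid-like cells were in neither test. Free RNA of a gene can be no more than its lowest mean UMIs per vehicle cell in any compared class, and with that much taken from the vehicle cells alone the highest median in mature neutrophil-like and monocyte-like cells was −0.35 (−0.43 to −0.18), and −0.35 (−0.40 to −0.088) without Ifi27l2a, which argues against free RNA as the whole cause there. It stays open in pro-B and pre-B cell-like (1.05, 0.48 to 1.47), immature and mature B cell-like (0.54, −0.017 to 1.53) and immature neutrophil-like cells (−0.28, but −0.25, −0.42 to 0.038, without Ifi27l2a). With 1 pool per group, a difference between the mice of the 2 pools cannot be told apart from the treatment.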
